A study of Mus musculus with 12 samples.

How the data were processed

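RNA was measured in 12 samples of tumours grown from Sq-1979 cells in mice, 3 each from vehicle, anti-PD1, regorafenib and combination treatment, with stranded libraries of polyadenylated RNA. The values are raw read counts per Ensembl gene, as deposited by the authors in a single table of 55,487 gene identifiers and 12 columns, all of which were used. The labels name cutadapt 2.4 for trimming, STAR 2.7.2a for alignment and the mouse build GRCm38, without parameters, and the counting tool, its strand setting and the annotation release are not stated in the sources used. GENCODE M21 supplied symbols, biotypes and coordinates: 54,435 identifiers equal those of that release with their version, 55,227 do so with the version ignored, and 55,141 have a symbol, of which 106 symbols are shared by more than 1 identifier. All samples held 0 counts for 22,937 identifiers.

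Library totals in counts were 23921871, 27605744 and 25833036 for vehicle, 23527359, 26699352 and 28209036 for anti-PD1, 23109578, 22591835 and 27626855 for regorafenib and 22815801, 27881867 and 27248310 for the combination. Low-count genes were removed with filterByExpr (minimum count 10, minimum total count 15), which left 16,974 genes holding 99.91% to 99.94% of the counts. Genes were tested with edgeR 4.0.16 under R 4.3.3 by quasi-likelihood F tests with robust estimation, in 1 fit of 4 group means over the 12 libraries with TMM factors (8 residual degrees of freedom, common biological coefficient of variation 0.227). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. The 8 comparisons were each treatment against vehicle, the combination against each single treatment, the interaction, and the average effect of each drug over both backgrounds. Levels are TMM-normalised CPM, and log2 CPM used a prior count of 2.

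Gene lists for cell types, interferon responses, vessels, signalling and tissue handling, 36 in all, of which 34 had at least 5 tested members, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The number of members past the gene test is given over all genes and adjusted over the list alone. Correlations of log2 fold changes across genes were described, and relations of list scores to Y-linked counts were tested with 1e+05 permutations and adjusted over 8 relations.

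The following rule chose the genes to name: in each comparison, of the genes past the threshold, the 6 higher and 6 lower with the smallest p and the 4 higher and 4 lower with the largest log2 fold change among those with a mean of at least 1 CPM; for each list described, up to 4 tested members with the smallest p; and a panel of 15 genes in every comparison. Where fewer than 10 genes passed, all were named, with the 3 higher and 3 lower of smallest p given as not past the threshold. Predicted or clone names and variable segments of antigen receptors were counted but not named. Groups, comparisons, tests, lists, panel and naming rule were fixed before the data were examined.

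Alternatives fixed at the same time were DESeq2 1.42.0, RLE factors, no filter on low counts, replicate number as a block, only the 6 samples of a pair, an additive model for the average effects, each library left out in turn, an estimated correlation between genes and fry (limma 3.58.1) for lists, and genes of at least 10 CPM for the correlations of fold changes. A covariate from 4 Y-linked genes and a fit of protein-coding genes only were added after the data were seen. The labels number replicates 1 to 3 in each group without saying that a number links samples of different groups. Where leaving out a library left 2 in its group, the spread was pooled over all groups.

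The edgeR procedure was tested on simulated data of the same size, with 50 genes changed by each of 1.5, 2, 3 and 5-fold. The simulated genes were drawn independently, with the same dispersion in all groups. Correlation between genes and unequal spread between groups are therefore left out, and false calls in the real libraries can differ. In combination against vehicle it recovered 14%, 72%, 80% and 88% of them, in the average regorafenib effect 56%, 74%, 96% and 98%, and in the interaction 4%, 34%, 62% and 80%, with 3 to 9 false calls per comparison among 16,759 unchanged genes. DESeq2 recovered 151 of 200 in combination against vehicle, with 45 false calls.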

Results

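The data describe tumours grown from Sq-1979 cells, a mouse line of head and neck squamous cell carcinoma, which were injected under the skin of male C3H/HeN mice in Matrigel. The mice were 6 weeks old at injection. From day 20 they received vehicle, regorafenib at 5 mg/kg per day (an inhibitor of several kinases, VEGF receptors, PDGF receptors and RAF among them), an antibody against the checkpoint receptor PD1, or both drugs, called the combination here. Polyadenylated RNA from 12 samples was sequenced, 3 in each of the 4 groups, and the question is what regorafenib and anti-PD1 do to the tumour alone and together. The libraries held 22591835 (regorafenib 2) to 28209036 (anti-PD1 3) counts each. Of 55,487 gene identifiers, 16,974 had enough counts to be tested. The labels do not say whether the 3 samples of a group came from 3 separate mice. The p-values of single genes therefore measure the spread between these samples. Those of lists by camera compare the genes of a list with all other genes, at a preset correlation of 0.01 between genes. They rest on that setting and are not a measure of the spread between samples. With an estimated correlation 0 lists passed in any comparison. Levels are in CPM, normalised for library size with TMM factors, with the SD over n = 3 libraries, and coordinates are those of mouse build GRCm38 in GENCODE M21.

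A panel of 15 genes that the treatments target or that mark immune cells, vessels and dividing cells was fixed before the data were examined. Cd274, which encodes PD-L1, averaged 69.0 ± 22.5 CPM (SD, n = 3) in vehicle tumours, 155 ± 74.6 with anti-PD1, 128 ± 48.2 with regorafenib and 157 ± 20.4 with the combination. Pdcd1, which encodes PD1, averaged 5.83 ± 1.09, 12.2 ± 5.38, 12.7 ± 3.37 and 10.25 ± 5.84 CPM in the same order. Gzmb, a cytotoxic granule protease, averaged 11.2 ± 4.18, 25.8 ± 15.6, 44.9 ± 27.5 and 22 ± 11.7 CPM. Arg1, an arginine-degrading enzyme of myeloid cells, averaged 1.06 ± 0.283, 2.61 ± 1.92, 9.2 ± 10.8 and 3.37 ± 2.35 CPM. The T cell genes Cd8a, Cd4, Foxp3 and Ifng had vehicle means of 14.9 ± 1.35, 22.8 ± 3.13, 3.38 ± 0.693 and 0.534 ± 0.0950 CPM, and their treated group means lay between 23.5 and 27.5, 30.2 and 38.3, 6.12 and 7.39, and 1.08 and 1.29 CPM. The chemokine gene Cxcl9 averaged 78.3 ± 40.4 CPM with vehicle and 119 to 137 CPM in the treated groups, and the immune receptor gene Cd40 8.35 ± 1.24 and 11.9 to 13.6 CPM. Among macrophage genes, Csf1r averaged 89.5 ± 9.81 CPM with vehicle and 84.0 to 114 CPM in the treated groups, and Mrc1 16.3 ± 8.31 and 14.7 to 37.2 CPM. The endothelial genes Kdr and Pecam1 averaged 15.3 ± 1.505 and 30.8 ± 3.51 CPM with vehicle, with treated means of 10.6 to 15.7 and 27.2 to 31.5 CPM. Mki67, which marks dividing cells, averaged 346 ± 57.8 CPM with vehicle and 315 to 352 CPM in the treated groups. By edgeR, 0 of the 15 genes passed in any of the 8 comparisons, with smallest adjusted p-values of 0.0841 for Cd274 in combination against vehicle and 0.0906 for Arg1 in the average regorafenib effect. 

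The average regorafenib effect asks what regorafenib did over both backgrounds, as the mean of its effect without anti-PD1 and its effect with it, and contrasts 6 regorafenib-treated libraries with the other 6. Mest, an imprinted gene of mesodermal tissue, fell 5.21-fold, from 13.4 ± 0.859 CPM (SD, n = 3) with vehicle and 9.19 ± 3.09 with anti-PD1 to 2.43 ± 0.544 with regorafenib and 1.86 ± 0.247 with the combination. Pcdh12, a vascular endothelial protocadherin, fell 3.59-fold, from 2.67 ± 0.377 and 2.48 ± 0.521 CPM to 0.888 ± 0.109 and 0.575 ± 0.141 CPM. Snhg17, a small nucleolar RNA host gene, rose 1.81-fold, from 45.8 ± 2.06 and 44.7 ± 4.17 CPM to 72.5 ± 5.59 and 92.0 ± 11 CPM. Oas1b, a member of the interferon-induced oligoadenylate synthetase family that the annotation classes as a polymorphic pseudogene, rose 1.93-fold, from 30.8 ± 2.22 and 34.9 ± 5.94 CPM to 61.8 ± 3.46 and 64.5 ± 8.21 CPM. In each of these 4 genes, and in Idh1, all 6 regorafenib-treated libraries lay on one side of all 6 others.

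The log2 fold change of Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465) was -2.38 ± 0.179 (SE), with an adjusted p of 0.000909. Mest shares 912 of its 3945 exonic bases with Copg2 on the opposite strand, and Copg2, looked up after its values were seen, had a log2 fold change of -0.24 (adjusted p 0.0408). Pcdh12 (ENSMUSG00000024440, chromosome 18, 38267089 to 38284402) had a log2 fold change of -1.84 ± 0.182 and an adjusted p of 0.00276, as did Oas1b (ENSMUSG00000029605, chromosome 5, 120812635 to 120824163) with 0.95 ± 0.093. Snhg17 (ENSMUSG00000085385, chromosome 2, 158353700 to 158361580) had 0.85 ± 0.074 and an adjusted p of 0.00181. Chka, a choline kinase (ENSMUSG00000024843, chromosome 19, 3851773 to 3894369), rose 1.55-fold with an adjusted p of 0.00287, and the collagen gene Col11a2 and the amine oxidase gene Aoc2 rose 1.94-fold and 1.91-fold. Tfr2, a transferrin receptor (ENSMUSG00000029716, chromosome 5, 137569840 to 137587481), fell 3.51-fold from 3.81 ± 1.20 CPM with vehicle to 0.915 ± 0.0622 with regorafenib. Idh1, the cytosolic isocitrate dehydrogenase (ENSMUSG00000025950, chromosome 1, 65158616 to 65186500), fell 1.82-fold from 58.6 ± 4.82 to 31.2 ± 1.49 CPM. The sperm calcium channel gene Catsper4 rose from 0.0660 ± 0.0254 CPM with vehicle to 0.751 ± 0.0458 with regorafenib, and Nell2 fell from 2.07 ± 0.572 to 0.128 ± 0.0915 CPM. The collagen gene Col8a2 and the nonclassical MHC class I gene H2-M5 fell 7.08-fold and 6.18-fold, and Clec4d, a lectin receptor of myeloid cells, rose 3.74-fold. Leaving aside Copg2, the 14 genes named so far for this effect kept their calls with each of the 12 libraries left out. Other large changes passed with all libraries and were lost when single libraries were left out: Omd, a small proteoglycan gene, fell 7.35-fold and kept its call in 6 of the 12 fits, the cytochrome gene Cyp4a12b fell 6.2-fold and kept it in 4, Hmga2, a chromatin factor, rose 4.79-fold and kept it in 4, Slfn4 rose 4.23-fold and kept it in 8, and the antibody gene Ighg3, covered below with the combination, kept it in 3. Slfn4 lost its call without vehicle 2, vehicle 3, anti-PD1 2 or combination 2. Omd lost it without any vehicle library, anti-PD1 2, combination 1 or combination 2, and Cyp4a12b without these, anti-PD1 3 or regorafenib 3. Hmga2 lost it without any vehicle or anti-PD1 library, regorafenib 1 or combination 2, and Ighg3 without any vehicle or regorafenib library, anti-PD1 1, anti-PD1 2 or combination 2.

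**Figure D1:**
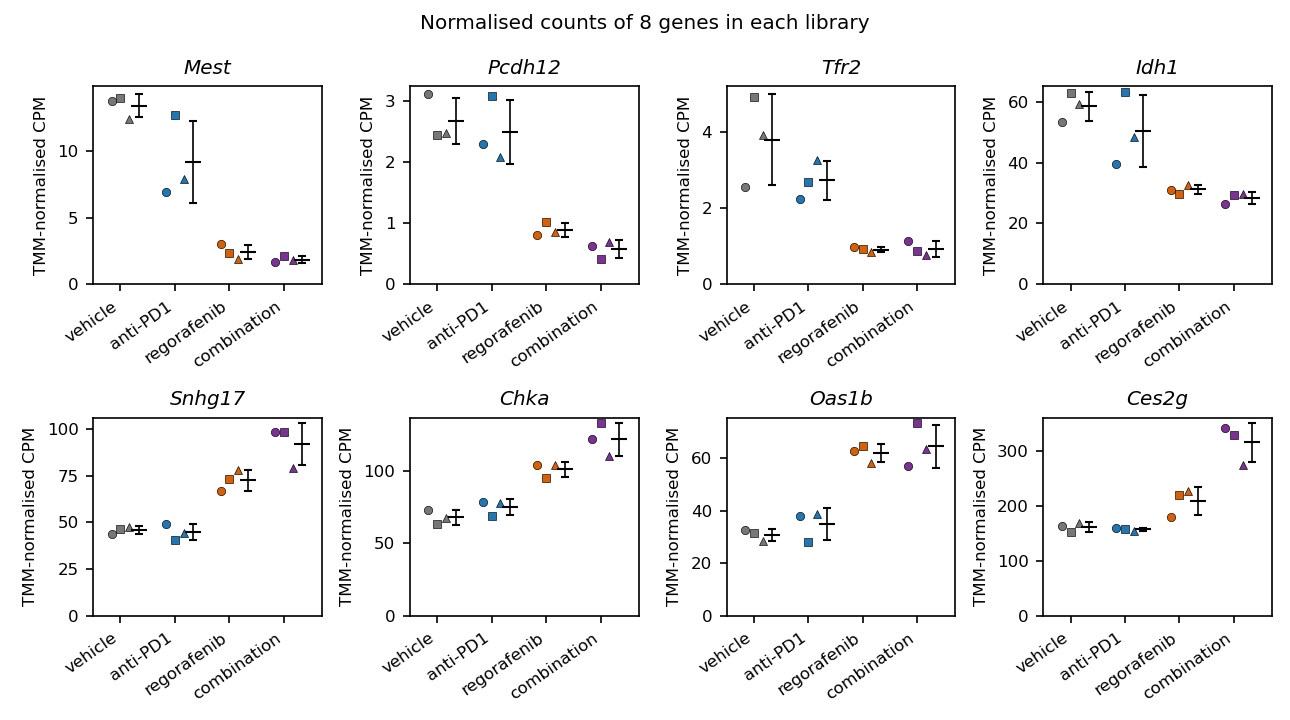
Level in TMM-normalised CPM (vertical axes, linear, starting at 0) of 8 named genes in each of the 12 libraries, by group, with the group mean and SD over n = 3 and marker shapes by replicate number. Mest, Pcdh12, Tfr2 and Idh1 are lower and Snhg17, Chka, Oas1b and Ces2g higher in the regorafenib and combination groups than with vehicle.

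In all, 1046 genes rose and 564 fell with regorafenib in this average effect by edgeR (adjusted p under 0.05), 310 of them by at least 2-fold, and 288 of the changed genes are counted here but not named, since they carry predicted or clone names or are variable segments of antigen receptors. DESeq2 called 1507 higher and 1228 lower. Leaving out 1 library gave 556 genes without vehicle 1, 556 without vehicle 2, 552 without vehicle 3, 460 without anti-PD1 2, 952 without anti-PD1 3, 998 without combination 1 and 522 without combination 2. With replicate number as a block the count was 504. It was also lower without a filter on low counts and was higher with the Y-linked covariate, by the counts given below.

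Vessel gene lists were lower with regorafenib. Of 15 tested genes of tip cells and VEGF-responsive vessels, 6 fell and 1 rose, among them the potassium channel subunit Kcne3 (log2 fold change -1.42, adjusted p 0.00736), the basement membrane gene Nid2 (-1.61, 0.00747), the peptide ligand Apln (-1.47, 0.0215) and the Notch ligand Dll4 (-0.89, 0.0237). Adjusted over the list alone, 6 were lower and 2 higher. The list had a median log2 fold change of -0.50 and passed camera, a test of a list against all other genes, with an adjusted p of 0.00742; its adjusted p = 0.681 with an estimated correlation. Of 24 endothelial genes, 3 fell, namely Emcn (-0.99, 0.00581), the tight junction gene Cldn5 (-0.95, 0.0139) and the receptor gene Tie1 (-0.50, 0.0245), and 17 of 24 were negative, with 4 lower adjusted over the list alone. The endothelial list had a median of -0.26 and an adjusted p of 0.00742, with adjusted p = 0.748 with an estimated correlation, and lost its call without combination 1 (median -0.15, adjusted p 0.103). Of 12 pericyte genes 9 were negative and 3 fell, the potassium channel genes Abcc9 (-0.63, 0.0137) and Kcnj8 (-0.72, 0.0262) and the respiratory chain gene Cox4i2 (-1.26, 0.0476), with 4 lower adjusted over the list alone. The pericyte list had a median of -0.52 and an adjusted p of 0.00742; its adjusted p = 0.541 with an estimated correlation, and fry, which tests a list against 0, gave an adjusted p of 0.00908. Kcne3, Nid2, Emcn, Cldn5 and Abcc9 kept their calls with each of the 12 libraries left out. Apln and Dll4 lost theirs without any vehicle library, anti-PD1 2 or combination 2, and Tie1 without vehicle 2, vehicle 3, anti-PD1 2, anti-PD1 3 or combination 2. Kcnj8 lost its call without any vehicle library, anti-PD1 2, regorafenib 3, combination 1 or combination 2, and Cox4i2 without these, anti-PD1 3 or combination 3.

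Connective tissue lists were lower as well. Of 21 fibroblast and matrix genes 19 were negative and 2 fell, the proteoglycan gene Lum (-2.20, adjusted p 0.0223), from 278 ± 23.7 CPM with vehicle to 72.9 ± 56.2 with regorafenib and 35.9 ± 16.9 with the combination, and the matrix glycoprotein gene Sparc (-1.44, 0.0459). The collagen genes Col5a2 (-1.09, 0.0720) and Col1a2 (-1.33, 0.108) did not pass, and adjusted over the list alone 2 genes were lower. The list had a median of -0.71 and an adjusted p of 7.36e-05, with adjusted p = 0.748 with an estimated correlation, and a median of -0.47 without anti-PD1 3 and -0.46 with Y-linked counts as a covariate, added after the data were seen. Of 10 factors of mesenchymal transition 9 were negative and 1, the cadherin gene Cdh2 (-1.73, 0.0295), fell, with 5 lower adjusted over the list alone; Snai2 (-0.43, 0.0501) and Snai1 (-0.997, 0.0551), transcription factors of that transition, did not pass. That list had a median of -0.43 and an adjusted p of 0.0020, with adjusted p = 0.748 with an estimated correlation. Its mean log2 difference from the vehicle mean was -0.046 in regorafenib 2, within the vehicle range of -0.097 to 0.097. The other regorafenib-treated libraries had -0.961 to -0.508, and anti-PD1 1, without the drug, had -0.74. Fibroblast genes had 0.028 in regorafenib 2 and -1.358 in anti-PD1 1. Lum lost its call without any vehicle library, anti-PD1 2 or combination 2, and Sparc and Cdh2 lost theirs without these, anti-PD1 3, regorafenib 1, regorafenib 3 or combination 1.

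Interferon and neutrophil lists were higher with regorafenib. All 24 tested genes of the type I interferon response were positive and 5 rose, among them Oas3 (0.97, adjusted p 0.00566), from 137 ± 13.7 CPM with vehicle to 324 ± 45.3 with regorafenib and 290 ± 56.1 with the combination, Oas2 (1.20, 0.00733), the antiviral GTPase gene Mx2 (0.70, 0.00748) and Xaf1 (0.53, 0.0217). Adjusted over the list alone, 17 were higher. The list had a median of 0.55 and an adjusted p of 7.42e-12, with adjusted p = 0.748 with an estimated correlation. Its mean log2 difference from the vehicle mean was 0.059 in combination 1, within the vehicle range of -0.092 to 0.115. Anti-PD1 3, without regorafenib, had 0.412, above regorafenib 3 (0.322) and combination 2 (0.343). All 15 neutrophil genes were positive and 2 rose, Clec4d (1.90, 0.0153) and the receptor gene Trem1 (1.09, 0.0322), with 11 higher adjusted over the list alone. Their median was 1.09 and their adjusted p 2.25e-06, with adjusted p = 0.646 with an estimated correlation and 0.0364 by fry. Oas3, Oas2, Mx2 and Clec4d kept their calls with each of the 12 libraries left out. Xaf1 lost its call without vehicle 2, vehicle 3 or combination 2, and Trem1 without any vehicle library, anti-PD1 2, anti-PD1 3, regorafenib 1, regorafenib 3, combination 1 or combination 2.

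Genes downstream of RAF, MEK and ERK, a kinase cascade that regorafenib can inhibit, were positive in 16 of 19 cases, and 4 rose and 2 fell. Spred3 (0.99, adjusted p 0.0137), which encodes an inhibitor of RAS signalling, and Dusp6 (0.52, 0.0196) and Dusp4 (0.71, 0.0305), which encode phosphatases that switch off MAP kinases, rose, while Spry4 (-1.46, 0.00496), which encodes another feedback inhibitor of receptor tyrosine kinase signalling, fell. Adjusted over the list alone, 9 were higher and 2 lower. The list had a median of 0.50 and an adjusted p of 0.00742, with adjusted p = 0.748 with an estimated correlation. Its mean log2 difference from the vehicle mean was 0.44, -0.356 and 0.385 in regorafenib 1 to 3 and 0.218 to 0.499 with the combination. The vehicle and anti-PD1 libraries had -0.232 to 0.077, so regorafenib 2 lay below all of them. Spry4 and Spred3 kept their calls with each of the 12 libraries left out. Dusp6 lost its call without vehicle 1, vehicle 2, anti-PD1 2 or combination 2, and Dusp4 without these, vehicle 3, regorafenib 1, regorafenib 3 or combination 1.

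Cytotoxic cell genes had a median of 0.54 with regorafenib (adjusted p 0.0110, adjusted p = 0.748 with an estimated correlation) and 1 of 20, the perforin gene Prf1 (1.03, adjusted p 0.0423), rose. This call ended without anti-PD1 2, regorafenib 1, regorafenib 2 or combination 3 (0.41, 0.49, 0.47 and 0.395, adjusted p 0.0638, 0.0635, 0.112 and 0.161), and Prf1 lost its own call without any vehicle library, anti-PD1 1, anti-PD1 2, regorafenib 1, regorafenib 2, combination 2 or combination 3. Of 26 interferon gamma response genes 1 rose, Nlrc5 (0.71, 0.0171), a regulator of MHC class I genes, which lost its call without combination 2. The interferon gamma list had a median of 0.34 and an adjusted p of 0.00742, with adjusted p = 0.748 with an estimated correlation, and this call ended without vehicle 3, anti-PD1 2, regorafenib 2 or combination 3 (0.21, 0.19, 0.16 and 0.16, adjusted p 0.0582, 0.0760, 0.118 and 0.0895).

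In all, 9 of 34 lists were higher and 5 lower in the average regorafenib effect by camera, 9 in total without anti-PD1 2 and 22 without anti-PD1 3. With an estimated correlation 0 of the 34 lists passed in any of the 8 comparisons (0 to 3 at an unadjusted p under 0.05), and fry called 2 lists here.

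**Figure D2:**
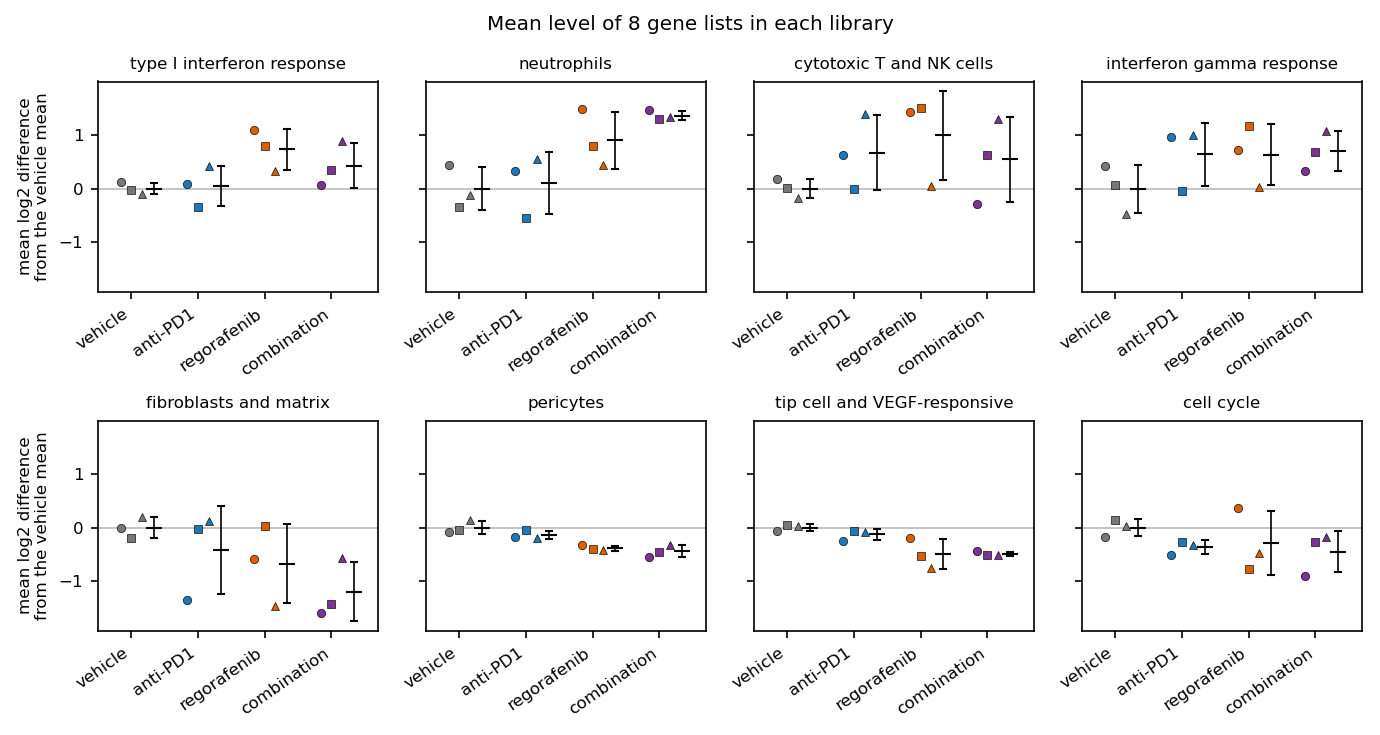
Mean log2 difference from the vehicle mean (vertical axes) of the tested members of 8 gene lists in each of the 12 libraries, by group, with the group mean and SD over n = 3. Marker shapes give the replicate number. The 6 pericyte scores with regorafenib run from -0.549 to -0.329 and those without it from -0.195 to 0.143.

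Regorafenib against vehicle gives the effect of the drug alone. Mest was the 1 gene that passed, 5.51-fold lower (log2 fold change -2.46 ± 0.253, SE, adjusted p 0.0203 by edgeR), with 13.4 ± 0.859 CPM in vehicle and 2.43 ± 0.544 in regorafenib tumours. Oas1b (1.01, adjusted p 0.0833), the membrane fusion gene Unc13d (0.59, 0.0854) and Catsper4 (adjusted p 0.0833, levels as above) were the closest of the higher genes, and Tfr2 (-2.06, 0.0833), the mevalonate kinase gene Mvk (-0.93, 0.0854) and Idh1 (-0.91, 0.0854) the closest of the lower ones, and none of the 6 passed. Mest lost its call without any 1 of the 6 libraries compared, which left 0 genes, with adjusted p up to 0.141. Unadjusted, 2398 genes had p under 0.05, and DESeq2 called 247 higher and 139 lower. More genes also passed without a filter on low counts and with the Y-linked covariate, by the counts given below. With replicate number as a block, or with only the 6 libraries in the fit, 0 genes passed.

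Regorafenib alone went with higher values of lymphocyte and interferon lists, but regorafenib 3 stood apart for the lymphocyte lists. The cytotoxic score, the mean log2 difference from the vehicle mean, was 1.436, 1.503 and 0.04 in regorafenib 1 to 3. The vehicle libraries had -0.176 to 0.17. The T cell score was 1.108, 1.166 and -0.165 in regorafenib 1 to 3, against -0.108 to 0.109 with vehicle. All 24 type I interferon genes were positive, with a median of 0.75, and the members with the smallest p were Oas3 (1.24), Mx2 (0.84), Oas2 (1.34) and Xaf1 (0.65). Over all genes 0 of them passed, and 19 were higher adjusted over the list alone; the list had an adjusted p of 2.22e-20 by camera and adjusted p = 0.510 with an estimated correlation. All 20 cytotoxic T and NK cell genes were positive, with a median of 1.11, among them Prf1 (1.55), Gzmb (2.00), Klre1 (2.05) and Klrd1 (1.13), of which 0 passed over all genes and 1 was higher adjusted over the list alone (adjusted p of the list 1.38e-08, adjusted p = 0.551 with an estimated correlation). T cell genes (0.87, adjusted p 9.04e-06, adjusted p = 0.564 with an estimated correlation) and neutrophil genes (1.02, 3.09e-05, adjusted p = 0.551 with an estimated correlation) were higher as lists. Pericyte genes had a median of -0.55 (adjusted p 0.00364; -0.32 without vehicle 3) and tip cell genes -0.38 (0.000795; -0.15 without regorafenib 3), with 0 and 5 lower adjusted over the list alone and adjusted p = 0.510 with an estimated correlation for both. Fibroblast genes had a median of -0.47 (adjusted p 0.000401, adjusted p = 0.564 with an estimated correlation), which became -1.13 without regorafenib 2 and lost its call without regorafenib 3 (-0.24, adjusted p 0.128). By camera 13 of 34 lists were higher and 8 lower.

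Combination against vehicle asks what both drugs did together. Snhg17 rose 2.01-fold to 92.0 ± 11 CPM, Aoc2 rose 2.29-fold to 22.9 ± 2.41 CPM, Col11a2 2.3-fold to 19.4 ± 2.87 CPM, Chka 1.79-fold to 122 ± 11.4 CPM and Ces2g, a carboxylesterase (ENSMUSG00000031877, chromosome 8, 104961718 to 104969537), 1.95-fold from 162 ± 8.62 to 316 ± 35.6 CPM. Mest fell 7.19-fold, Pcdh12 4.62-fold, Tfr2 4.12-fold and Idh1 2.06-fold. Lum fell 7.74-fold to 35.9 ± 16.9 CPM, Omd 13.8-fold from 24.7 ± 11.4 to 1.78 ± 0.533 CPM, Col8a2 10.9-fold and H2-M5 11.9-fold. Each of these calls but that of Mest ended without any 1 vehicle library; those of Idh1, Lum, H2-M5 and Omd also ended without combination 1 or combination 2, that of Omd also without combination 3 (adjusted p up to 0.158), that of Col8a2 without combination 1 and that of Tfr2 without combination 2.

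Constant regions of antibodies were among the largest rises. Ighg2c rose from 0.694 ± 0.634 CPM with vehicle to 21.5 ± 1.40 (log2 fold change 4.95, adjusted p 0.0499), Igkc from 3.52 ± 1.68 to 89.8 ± 70.2 (4.68, 0.0421) and Ighg2b from 2.13 ± 0.422 to 50.9 ± 71.8 (4.58, 0.0352). Ighg3 averaged 0.0268 ± 0.0233 CPM with vehicle and 4.34 ± 2.99 with the combination (adjusted p 0.0113). Ighg2c kept its call in 0 of 6 fits that left out a library (adjusted p up to 0.151), Igkc and Ighg2b only without combination 3 (up to 0.148 and 0.129), and Ighg3 lost its call without any 1 vehicle library. Ighg2c measured 20.24, 21.2 and 23 CPM in the 3 combination libraries and 4.667, 0.07678 and 26.76 in the anti-PD1 libraries. Ighg2b measured 133.6 CPM in combination 1 against 5.499 and 13.51 in the others, and without combination 1 its log2 fold change was 2.15 (adjusted p 0.0946). The list of B and plasma cell genes did not pass in any comparison (smallest adjusted p 0.0714).

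By edgeR 853 genes rose and 393 fell with the combination, 407 of these 1246 by at least 2-fold and 254 counted but not named, with the smallest adjusted p-values for Mest (0.00583), Snhg17 (0.00829) and Unc13d (0.00951, 1.72-fold higher). The sorting nexin gene Snx7 and the vesicle coat gene Sec23a fell 1.83-fold and 1.51-fold with an adjusted p of 0.0113, and both calls also ended without combination 2. DESeq2 called 1408 higher and 1155 lower. Each of vehicle 1, vehicle 2 and vehicle 3, when left out, ended every call but that of Mest, and 23 genes passed without combination 1 and 12 without combination 2. With replicate number as a block 11 genes passed. Fewer than the 1246 passed without a filter on low counts. More passed with the Y-linked covariate and with only the 6 samples of the pair, by the counts given below.

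Genes of non-coding biotypes, a class chosen after its values were seen, were frequent among the genes that rose. A Fisher exact test against protein-coding genes gave an odds ratio of 2.243 (p = 6.68e-22). Since the class was picked from the same data and genes are not independent, this p-value lends no support. Of 2696 such genes, which leave out antigen-receptor genes, polymorphic pseudogenes and genes without a biotype, 242 rose and 8 fell, and of 14,198 protein-coding genes 598 rose and 385 fell. Among the non-coding ones 59 of 461 lincRNAs, 33 of 252 processed transcripts, 30 of 397 antisense transcripts and 68 of 307 genes awaiting experimental support rose, and 0 genes of these 4 classes fell, while of 886 processed pseudogenes 8 rose and 7 fell. The median log2 fold change of all tested non-coding genes was 0.28 and that of protein-coding genes -0.01. Non-coding genes took 1.932% to 1.994% of the counts in the vehicle libraries and 2.182% to 2.462% in the combination libraries. They took 1.993% to 2.203% in the anti-PD1 libraries and 2.058% to 2.31% in the regorafenib libraries. These ranges overlap that of the combination, and anti-PD1 1 (2.203%), without regorafenib, lay above combination 3 (2.182%). In combination against anti-PD1, 74 non-coding genes rose and 0 fell, and in the average regorafenib effect 274 rose and 14 fell.

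Matrix and vessel lists were lower and neutrophil and interferon lists higher with the combination. Of 21 fibroblast and matrix genes 20 were negative and 1, Lum, fell, with 2 lower adjusted over the list alone, a median of -1.27 (-0.81 with the Y-linked covariate) and an adjusted p of 1.19e-06, adjusted p = 0.807 with an estimated correlation. All 15 neutrophil genes were positive and 1, Clec4d (1.95, adjusted p 0.0460), rose, with 8 higher adjusted over the list alone, a median of 1.34 and an adjusted p of 2.51e-05, adjusted p = 0.807 with an estimated correlation. Of 26 interferon gamma response genes 25 were positive and Nlrc5 (1.05, 0.0207) rose, also the 1 gene higher adjusted over the list alone, with a median of 0.64 and an adjusted p of 2.51e-05, adjusted p = 0.807 with an estimated correlation. Of 28 cell cycle genes 27 were negative and 0 passed, with a median of -0.46 and an adjusted p of 8.86e-05, adjusted p = 0.807 with an estimated correlation, and -0.27 without combination 1. Pericyte genes had a median of -0.66 (adjusted p 0.0158, 0.0253 by fry, adjusted p = 0.807 with an estimated correlation) with 0 of 12 past the test, and 4 of 15 tip cell genes fell, Nid2 (-1.91), Kcne3 (-1.64), Dll4 (-1.10) and Igfbp3 (-0.78), with a median of -0.49 (adjusted p 0.0158, adjusted p = 0.807 with an estimated correlation). The tip cell call ended without combination 3 (-0.53, adjusted p 0.0862). In the endothelial list Emcn (-1.24) and Tie1 (-0.69) fell, and its median of -0.34 (adjusted p 0.00555, adjusted p = 0.807 with an estimated correlation) was -0.15 without combination 1 (adjusted p 0.215). Type I interferon genes had a median of 0.46 (adjusted p 8.86e-05, adjusted p = 0.807 with an estimated correlation) and 5 of 24 rose, among them Oas3 (1.08), Oas2 (1.19), Mx2 (0.69) and Xaf1 (0.69), and the list lost its call without combination 3 (0.19, adjusted p 0.120). Of the members named here Clec4d, Igfbp3, Oas2, Mx2 and Xaf1 lost their calls without any 1 of the 6 libraries, and Lum, Nlrc5, Nid2, Kcne3, Dll4, Emcn, Tie1 and Oas3 without any of them but combination 3. By camera 8 of 34 lists were higher and 6 lower, and 9 in total passed without combination 3.

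Combination against anti-PD1 gives the effect of regorafenib on top of the antibody. Snhg17 rose 2.06-fold from 44.7 ± 4.17 to 92.0 ± 11 CPM, Ces2g 2-fold from 158 ± 2.55 to 316 ± 35.6 CPM, the phospholipase gene Plch2 1.87-fold from 104 ± 5.50 to 195 ± 24.6 CPM, Ltb4r1, a leukotriene B4 receptor, 1.89-fold from 7.86 ± 0.667 to 14.8 ± 0.585 CPM and the transcription regulator gene Crebzf 1.62-fold from 41.9 ± 2.47 to 67.7 ± 5.90 CPM. Mest fell 4.93-fold and Pcdh12 4.3-fold. The adjusted p was 0.00878 for each of these 7 genes and for Aoc2, which rose from 10.8 ± 1.07 to 22.9 ± 2.41 CPM. The troponin gene Tnnt2 rose 3.54-fold from 26.9 ± 5.06 to 95.3 ± 31.1 CPM (adjusted p 0.0159), A3galt2, a glycosyltransferase gene, 3.77-fold (0.0259) and the autophagy gene Atg9b 2.95-fold (0.0274). Col8a2 fell 6.56-fold (adjusted p 0.0274), the GTPase gene Rhoq from 64.7 ± 5.68 to 44.2 ± 1.26 CPM (0.0197) and Snx7 from 22.7 ± 1.94 to 14.4 ± 1.65 CPM (0.0218). H2-M5 averaged 2.41 ± 1.28 CPM with anti-PD1 and 0.184 ± 0.0854 with the combination (adjusted p 0.0159), Nell2 1.36 ± 0.872 and 0.0242 ± 0.0418 (0.0218) and Ighg3 0.112 ± 0.128 and 4.34 ± 2.99 (0.0159). Each of these calls ended without anti-PD1 2, anti-PD1 3 or combination 2, those of H2-M5, Rhoq, Snx7, Nell2, A3galt2, Tnnt2, Atg9b and Col8a2 also without combination 1, and that of Col8a2 also without combination 3.

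By edgeR 288 genes rose and 38 fell in this comparison, 117 of these 326 by at least 2-fold and 72 counted but not named, and DESeq2 called 795 higher and 365 lower. Leaving out anti-PD1 2, anti-PD1 3 or combination 2 left 0 genes in each case, and leaving out combination 1 left 21. With replicate number as a block, or with only the 6 libraries in the fit, 0 genes passed. Of 15 neutrophil genes 14 were positive, with a median of 1.14, 0 past the test over all genes and 3 higher adjusted over the list alone (adjusted p 1.90e-05, adjusted p = 0.769 with an estimated correlation). Fibroblast and matrix genes had a median of -0.91 with 19 of 21 negative and 0 past the test (adjusted p 0.000264, adjusted p = 0.998 with an estimated correlation), -0.55 without anti-PD1 3, -1.38 without combination 3 and -0.39 with the Y-linked covariate (adjusted p 0.00364). In the RAF-MEK-ERK list Spred3 (1.22, adjusted p 0.0434) rose, Spry4 (-1.25, 0.0542), Dusp6 (0.57, 0.0856) and the transcription factor gene Etv4 (1.70, 0.125) did not pass, and the median was 0.59 with 3 higher and 1 lower adjusted over the list alone (adjusted p 0.00102, adjusted p = 0.869 with an estimated correlation). Spred3 lost its call without any 1 of the 6 libraries. All 7 tested mitochondrially encoded genes were positive, with a median of 0.37 and 6 higher adjusted over the list alone (adjusted p 0.000448, adjusted p = 0.839 with an estimated correlation). By camera 5 of 34 lists were higher and 4 lower, and 14 in total passed without anti-PD1 2.

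**Figure D3:**
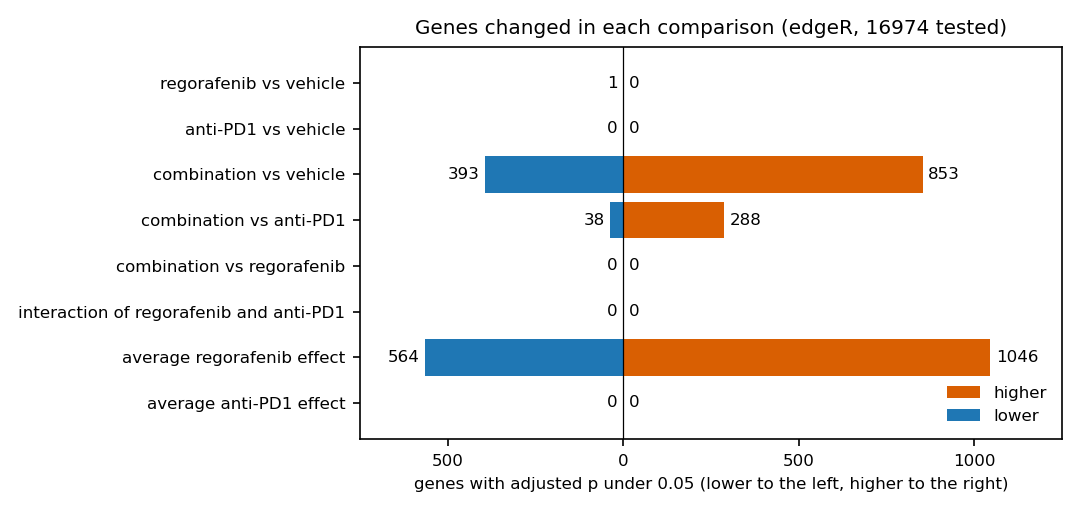
Number of genes past the threshold (adjusted p under 0.05, edgeR) that were higher and lower in each of the 8 comparisons, out of 16,974 tested. The average regorafenib effect has 1046 higher and 564 lower genes, and the comparisons of anti-PD1 against vehicle, combination against regorafenib, the average anti-PD1 effect and the interaction have 0.

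Anti-PD1 against vehicle gives the effect of the antibody alone, and 0 genes passed by edgeR. Genes induced by interferon gamma were higher as a list (adjusted p 1.89e-15 by camera, adjusted p = 0.666 with an estimated correlation): all 26 were positive, with a median of 0.69, and those with the smallest p were Cd274 (1.17), the guanylate-binding protein gene Gbp2 (0.91) and the GTPase genes Tgtp1 (0.73) and Tgtp2 (0.63). All 28 cell cycle genes were negative, with a median of -0.36 (adjusted p 1.55e-09, adjusted p = 0.666 with an estimated correlation), among them the cyclin gene Ccne2 (-0.47), the S-phase factor genes E2f1 (-0.58) and Pcna (-0.31) and Ccnb2 (-0.56). Over all genes and adjusted over the list alone 0 members of either list passed. The interferon gamma score, the mean log2 difference from the vehicle mean, was 0.964, -0.036 and 1.001 in anti-PD1 1 to 3. The vehicle libraries had 0.412, 0.062 and -0.475, so anti-PD1 2 lay within their range. T cell genes (0.70), cytotoxic genes (0.78), regulatory T cell genes (0.70) and checkpoint genes (1.04) were higher with adjusted p-values of 2.88e-06, 4.69e-07, 0.000748 and 1.53e-06, and adjusted p = 0.666 with an estimated correlation for each. These 4 lists lost their calls without anti-PD1 3, with medians of 0.26, 0.42, 0.09 and 0.42 (adjusted p 0.239, 0.0615, 0.307 and 0.0615). The genes closest to the threshold were Bbx (0.40), Rapgef6 (0.40) and the integrin gene Itgb8 (2.06) among the higher and Shox2 (-0.74), Gnl3 (-0.35) and Fjx1 (-0.54) among the lower, each with an adjusted p of 0.866. Unadjusted, 878 genes had p under 0.05, and DESeq2 called 2 genes higher. By camera 7 of 34 lists were higher and 4 lower, 18 in total without anti-PD1 2 and 7 without anti-PD1 3.

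The average anti-PD1 effect is the mean of the antibody's effect without and with regorafenib, and 0 genes passed by edgeR, with 1485 at an unadjusted p under 0.05 and 3 called higher by DESeq2. Cell cycle genes were negative in all 28 cases, with a median of -0.30 (adjusted p 4.38e-08), -0.09 without regorafenib 1, fibroblast and matrix genes in 20 of 21, with a median of -0.43 (adjusted p 3.48e-06), -0.23 without regorafenib 2 and -0.285 with the Y-linked covariate, and interferon gamma genes were positive in 23 of 26, with a median of 0.35 (adjusted p 3.37e-07). Each had 0 members past the test over all genes or adjusted over the list alone, and adjusted p = 0.932 with an estimated correlation. The fibroblast score was -1.358, -0.033 and 0.132 in anti-PD1 1 to 3, against -0.198 to 0.201 with vehicle. In anti-PD1 against vehicle the fibroblast median was 0.033 without anti-PD1 1 (adjusted p 0.746 by camera). Members with the smallest p were Ccne2 (-0.33), Postn (-0.43), a matrix protein gene, and Cd274 (0.73). The genes closest to the threshold were Lnpep (0.34), Parp4 (0.33) and Ighg2c (5.05) among the higher and Ddx31 (-0.23), Scd4 (-1.21) and Rflnb (-0.21) among the lower, with an adjusted p of 0.558. The 3 lists became 5 to 13 when single libraries were left out, 13 without anti-PD1 2 or regorafenib 1, 11 without combination 1, 10 without anti-PD1 3, 8 without vehicle 1, vehicle 2, anti-PD1 1 or regorafenib 3, 7 without regorafenib 2 or combination 3, 6 without combination 2 and 5 without vehicle 3.

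Combination against regorafenib gives the effect of anti-PD1 on top of regorafenib, and 0 genes passed by edgeR, with 925 at an unadjusted p under 0.05 and 4 called higher by DESeq2. The closest were Ighg3, with 0.0698 ± 0.0285 CPM against 4.34 ± 2.99 (adjusted p 0.402), then Ces2g (0.59), the acyl-CoA thioesterase gene Acot4 (1.54), Rhoq (-0.39), the cell cycle kinase gene Wee1 (-0.40) and the death-associated kinase gene Dapk2 (-0.73), each with an adjusted p of 0.856. Of 24 type I interferon genes 23 were negative, with a median of -0.32, 0 past the test over all genes or adjusted over the list alone, and values of -0.44 for Usp18 and -0.56 for Isg15, an interferon-induced protease and a ubiquitin-like protein. The list had an adjusted p of 1.21e-05, and adjusted p = 0.801 with an estimated correlation, and its median was -0.10 without regorafenib 1, -0.15 without combination 1, -0.55 without combination 3 and -0.19 with the Y-linked covariate. By camera 2 of 34 lists were higher and 8 lower, 17 in total without regorafenib 3 and 16 without combination 2 or combination 3.

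The interaction asks whether the effect of regorafenib differed with and without anti-PD1, and by edgeR 0 genes passed, with 449 at an unadjusted p under 0.05 and 0 by DESeq2. Immune lists differed in a negative direction. All 20 cytotoxic genes were negative, with a median of -1.10 and values of -2.48 for Gzma, -2.23 for Gzmb and -2.28 for Klrb1c, which encode granule proteases and an NK cell receptor (adjusted p 5.80e-13, adjusted p = 0.600 with an estimated correlation), and the median was -0.67 with the Y-linked covariate. All 22 T cell genes were negative, with a median of -0.98 (adjusted p 4.73e-10, adjusted p = 0.600 with an estimated correlation), -0.54 without anti-PD1 3, -1.49 without combination 3 and -0.59 with the Y-linked covariate. All 26 interferon gamma genes were negative too, with a median of -0.61 (adjusted p 1.86e-09, adjusted p = 0.600 with an estimated correlation), -0.34 without regorafenib 2. In each list 0 members passed over all genes or adjusted over the list alone. The genes closest to the threshold were the carboxylesterase genes Ces2e (0.91) and Ces2g (0.63) and Sox10, with 0.413 ± 0.0681 CPM in the combination and 0.0120 ± 0.0207 with anti-PD1, among the higher and Rnase1 (-2.46), Rnf125 (-1.15) and Fbxo33 (-0.56) among the lower, with an adjusted p of 1.00. By camera 7 of 34 lists were higher and 11 lower.

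Across all 16,974 genes, the log2 fold changes of regorafenib without and with anti-PD1, which share no library, had a Pearson r of 0.568 and a Spearman rho of 0.559, and those of anti-PD1 without and with regorafenib had an r of 0.210 and a rho of 0.227. Genes are not independent replicates. Without anti-PD1 1 the second r was 0.017. Of the genes that rose in combination against anti-PD1, 282 also rose in the average regorafenib effect, and 38 fell in both, against 17.8 and 1.26 if the sets were independent, which they are not since they share libraries. Combination against vehicle shared 668 higher and 309 lower genes with the average effect, and 0 genes moved in opposite directions. Both contrasts use the vehicle and combination libraries with the same signs, so this overlap and this 0 lend no support.

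The host is male, and the sex of the tumour line is not given, so 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y) were summed as a possible measure of host-cell share after the data were seen. They averaged 30.0 ± 4.08 CPM in vehicle, 30.7 ± 10.7 in anti-PD1, 30.6 ± 11.9 in regorafenib and 24.9 ± 8.6 in combination libraries. Over the 12 libraries they correlated with the fibroblast score (r = 0.853, rho = 0.776, permutation p = 0.0009, adjusted p = 0.00459 over 8 relations), the macrophage score (r = 0.812, rho = 0.832, permutation p = 0.00172, adjusted p = 0.00459) and the T cell score (r = 0.706, rho = 0.769, permutation p = 0.0131, adjusted p = 0.0210). Without regorafenib 3 and combination 1, the libraries farthest from the median, r was 0.746, 0.747 and 0.573, and within groups it was 0.928, 0.913 and 0.854. Dendritic cell, MHC class II and cytotoxic scores had r of 0.812, 0.782 and 0.646 (adjusted p 0.00459, 0.00664 and 0.0374 by permutation). The pericyte score (r = 0.324, rho = 0.273, permutation p = 0.301) and the neutrophil score (r = -0.04, rho = 0.189, permutation p = 0.901) did not correlate with them.

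**Figure D4:**
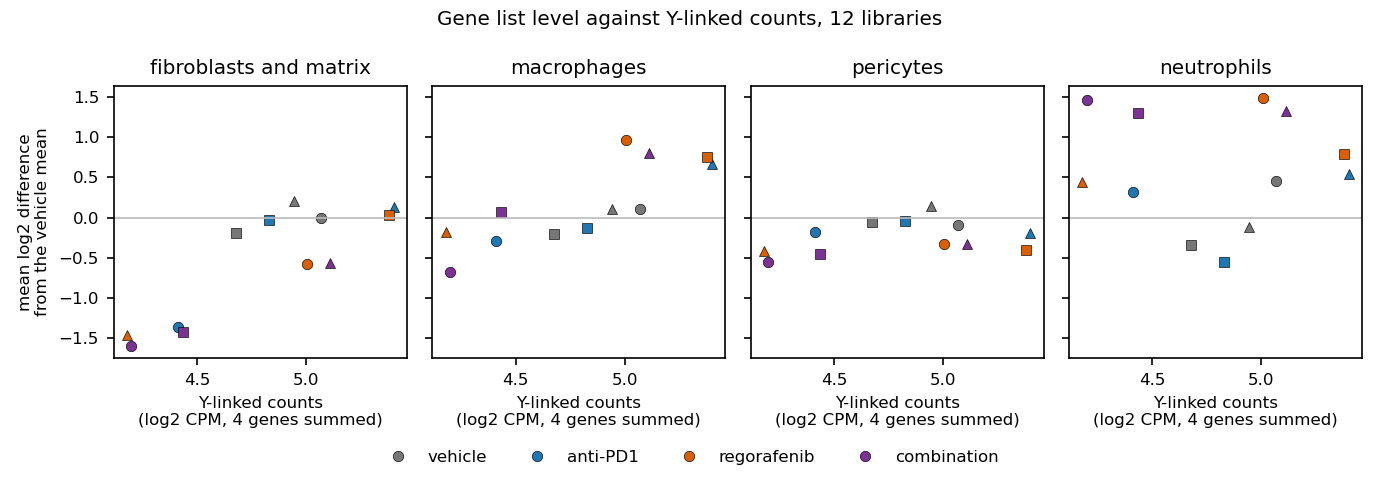
Mean log2 level relative to the vehicle mean (vertical axes) of the fibroblast, macrophage, pericyte and neutrophil lists against the summed counts of 4 Y-linked genes (horizontal axes, log2 CPM) in the 12 libraries. Colours give the group and marker shapes the replicate number. Fibroblast and macrophage levels are higher where Y-linked counts are higher (r = 0.853 and 0.812), and pericyte and neutrophil levels do not follow them (r = 0.324 and -0.04).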

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

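The tests of gene length bias, of host-cell share for the pericyte and fibroblast lists and of both explanations for 5 immune lists, the class of non-coding genes and the Y-linked covariate were chosen only after the results were seen. The first results of this part are lists whose regorafenib effect differed with and without anti-PD1 by a test of the interaction, and non-coding genes in combination against vehicle and 2 lists of the average regorafenib effect follow. All of the interaction calls are lost with an estimated correlation (adjusted p = 0.600 to 0.760), and by edgeR 0 genes passed the interaction (449 at an unadjusted p under 0.05, 0 by DESeq2).

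The median interaction, on the log2 scale, was -1.102 for cytotoxic T and NK cell genes (adjusted p 5.80e-13), -0.977 for T cell genes (4.73e-10), -0.995 for checkpoint genes (2.02e-08), -0.61 for interferon gamma genes (1.86e-09), -0.385 for type I interferon genes (1.11e-07) and -0.221 for MHC class I genes (0.000182). It was 0.369 for mitochondrially encoded genes (adjusted p 5.10e-06). These 7 lists kept their calls with each of the 12 libraries left out, with medians that moved by over 1.5 times for T cells (-0.544 without anti-PD1 3, -1.487 without combination 3), checkpoints (-0.659 without regorafenib 2, -1.549 without combination 3), interferon gamma (-0.341 without regorafenib 2), MHC class I (-0.369 without anti-PD1 2, -0.357 without regorafenib 3) and type I interferon (-0.245, -0.203, -0.585, -0.248 and -0.674 without anti-PD1 3, regorafenib 1, regorafenib 3, combination 1 and combination 3).

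Other lists lost their calls without the libraries named first, with the median then, and moved by over 1.5 times with the call kept without those named last. Regulatory T cells: -0.78 (adjusted p 0.00279), without anti-PD1 3 -0.259, regorafenib 1 -0.56, regorafenib 2 -0.512 or combination 1 -0.45; kept, combination 3 -1.488. Dendritic cells: -0.815 (0.000115), without anti-PD1 3 -0.32 or combination 1 -0.515; kept, combination 3 -1.257. Macrophages: -0.512 (0.000182), without anti-PD1 3 -0.145, regorafenib 1 -0.382 or combination 1 -0.238; kept, regorafenib 3 -0.813 and combination 3 -0.992. M2-type macrophage genes: -0.413 (0.0199), without vehicle 1 -0.136, vehicle 2 -0.311, anti-PD1 1 -0.41, anti-PD1 3 0.103, regorafenib 1 0.138 or combination 1 -0.007; kept, vehicle 3 -0.931, anti-PD1 2 -0.647, regorafenib 3 -0.633 and combination 3 -0.668. MHC class II: -0.57 (0.00107), without anti-PD1 3 -0.216, regorafenib 2 -0.148 or combination 1 -0.317; kept, regorafenib 3 -0.876. Hypoxia response: 0.412 (0.000318), without regorafenib 2 0.229 or combination 1 0.063; kept, vehicle 2 0.206, anti-PD1 3 0.235 and regorafenib 3 0.663. Smooth muscle: 0.563 (0.0228), without vehicle 2 0.236, anti-PD1 1 0.394, regorafenib 2 0.368 or combination 3 0.43. Skeletal muscle: 0.505 (0.00862), without vehicle 3 0.142, anti-PD1 2 0.258, regorafenib 1 0.023 or combination 3 -0.272; kept, anti-PD1 3 0.783, regorafenib 2 1.004 and combination 1 0.847. Cell cycle: 0.138 (0.0213), without vehicle 2 0.059, anti-PD1 1 0.044, regorafenib 2 -0.096, regorafenib 3 0.007, combination 2 0.014 or combination 3 -0.017; kept, regorafenib 1 0.527 and combination 1 0.309. RAF-MEK-ERK output: 0.179 (0.0133), without anti-PD1 1 0.153, regorafenib 2 -0.001 or combination 1 0.16; kept, vehicle 1 0.276, anti-PD1 2 0.284 and regorafenib 3 0.325. Nerve and Schwann cells: 0.083 (0.0199), without vehicle 2 0.076, anti-PD1 2 0.173, regorafenib 1 0.137, regorafenib 2 0.115 or combination 2 0.053; kept, vehicle 1 0.265, vehicle 3 0.19, anti-PD1 1 0.545, regorafenib 3 0.383, combination 1 0.214 and combination 3 0.377. With the Y-linked covariate, smooth muscle (0.488, adjusted p 0.0625), RAF-MEK-ERK output (0.138, 0.0634) and M2-type macrophage genes (0.03, 0.166) lost their calls, and T cell (-0.588), checkpoint (-0.652), cytotoxic (-0.674), regulatory T cell (-0.401), dendritic cell (-0.404), macrophage (-0.154), MHC class II (-0.21), hypoxia (0.241) and nerve and Schwann cell genes (0.26) moved by over 1.5 times.

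Immune lists had a negative interaction, that is, a lower regorafenib effect with anti-PD1 than without, as for T cells with medians of -0.163 and 0.867. The cytotoxic list kept its call in 12 of 12 fits that left out a library, with medians of -1.557 to -0.798. This argues against a single library as the only source of its negative median. It does not show a difference beyond the spread between libraries, since the call is lost with an estimated correlation (adjusted p = 0.600). Cytotoxic scores ran from 0.04 to 1.503 with regorafenib, from -0.28 to 1.297 with the combination and from -0.009 to 1.383 with anti-PD1. A single library stays open for regulatory T cells, dendritic cells, macrophages, M2-type genes and MHC class II. These lists lost their calls without anti-PD1 3 and also without combination 1, and kept them in as few as 6 of 12 fits. Host-cell share of each tumour stays open for the cytotoxic list (-0.674 with the Y-linked covariate, adjusted p 4.44e-10) and for these 5, of which 4 lost the call or at least 50% of the median: macrophages -0.154, M2-type 0.03, MHC class II -0.21 and dendritic cells -0.404, beside -0.401 for regulatory T cells. A biological dependence of the regorafenib effect on anti-PD1 stays open and cannot be told apart from host-cell share here. The labels do not give the sex of the tumour line. Xist, the RNA of the inactive X chromosome, measured 412.6 to 1405 CPM in all 12 libraries. The hosts were male, so tumour cells are its likelier source, which was not tested. Chance in the grouping cannot be excluded for the number of lists: 38 of 100 splits gave as many as the real 18, the highest other 23.

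Non-coding genes were frequent among those higher in combination than in vehicle, with a median log2 fold change of 1.295 for the 242 called. Genomic DNA in the libraries stays open: for the summed counts of 1738 receptor genes the log2 ratio of the highest combination library over the lowest vehicle library was 0.685 and that of the means 0.409, under the bound of 1.295 set before, but the called genes are chosen for their size and the median of all 2696 tested non-coding genes was 0.281. A larger share of nuclear RNA stays open: 20 nuclear lncRNAs had a median log2 change of 0.513, of which 15 were positive and 7 called, while Mirg (-2.97), Miat (-2.698), Rian (-2.368), Meg3 (-1.845) and Peg13 (-0.032) were negative. Gene length bias stays open too, with a Spearman correlation of 0.177 between log2 change and exonic length over 14,198 protein-coding genes. A response of these genes to the drugs was not tested apart from these explanations.

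Pericyte genes and fibroblast genes were lower with regorafenib as lists, and both calls are lost with an estimated correlation (adjusted p = 0.541 and adjusted p = 0.748 with an estimated correlation). For pericytes, a lower share of host cells stays open, since its test was set after the results were seen. The neutrophil median was 1.089 in the same comparison, but the neutrophil score did not follow Y-linked counts (r = -0.04), so it cannot decide this. Y-linked counts changed by -0.17 and the pericyte median was -0.515. The pericyte score did not follow Y-linked counts either (r = 0.324), and the pericyte median was -0.442 with the Y-linked covariate (adjusted p 0.00934 by camera). A single library as the only source of the negative pericyte median is argued against by 12 of 12 fits that kept the camera call, with medians of -0.635 to -0.38. For fibroblasts, host-cell share of each tumour stays open, since with the Y-linked covariate the median was -0.46 instead of -0.714 and the fibroblast score followed Y-linked counts within groups (r = 0.928). A fall of pericyte genes in response to regorafenib is a hypothesis found and tested on the same data.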

How the results depend on the processing

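The Y-linked covariate and the fit of protein-coding genes only were chosen only after the results were seen. No named gene past the threshold turned direction in any setting run: of these 102 results, 102 kept their side of the threshold with DESeq2, RLE factors and the covariate, 76 without a filter on low counts, 38 with replicate number as a block, 86 of 90 in the fit of protein-coding genes, 36 of 56 with only the 6 samples of the pair and 45 of 46 in the additive model. Of 100 list calls, 100 kept direction and call with the block, 99 with RLE factors, 99 without the filter, 97 with protein-coding genes, 83 with the covariate, 3 with fry and 0 with an estimated correlation. The replicate numbers show no link between samples of different groups: 2 of 18 pairs with the same number in different groups correlated above 0.1, with a median of -0.052, and the block spends degrees of freedom. Other causes below were not tested.

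With no filter on low counts, genes changed numbered 6 in regorafenib against vehicle, 663 in combination against vehicle (656 shared with the 1246) and 959 in the average regorafenib effect (943 shared), and lists changed 5 in the average anti-PD1 effect; the cause was not tested. With replicate number as a block they numbered 0 in regorafenib against vehicle, 11 in combination against vehicle, 0 in combination against anti-PD1 and 504 in the average regorafenib effect (501 shared). With the Y-linked covariate they numbered 287, 2411 (1245 shared), 812 (326 shared) and 3390 (1610 shared) in the same 4 comparisons, and lists changed 5 in combination against regorafenib and 13 in the average anti-PD1 effect; the cause was not tested. With protein-coding genes only, 829 changed in combination against vehicle, 806 of them shared, where fewer genes were tested. With only the 6 samples of the pair, 0 changed in regorafenib against vehicle and 2068 in combination against vehicle (1119 shared). In combination against anti-PD1 0 changed, and in combination against regorafenib 1. There the spread came from those 6 samples alone, and the groups differed in spread. The chi-square per gene between 2 libraries of a group was 11.4 to 17.87 for vehicle and 37.52 to 90.32 for anti-PD1. It was 62.3 to 117.8 for regorafenib and 29.77 to 59.05 for the combination. The cause of these counts was not tested. DESeq2 called 386 in regorafenib against vehicle, 2 in anti-PD1 against vehicle and 2563 in combination against vehicle (1230 shared). It called 1160 in combination against anti-PD1 (317 shared) and 4 in combination against regorafenib. In the average regorafenib effect it called 2735 (1588 shared) and in the average anti-PD1 effect 3. The cause was not tested. In the simulated combination against vehicle, DESeq2 made 45 false calls beside 151 recovered genes, and edgeR made 5 false calls. The larger DESeq2 counts can therefore not be read as further true changes.

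With an estimated correlation 0 lists changed in each of the 8 comparisons. With fry 0 lists changed in regorafenib against vehicle, anti-PD1 against vehicle, combination against anti-PD1, combination against regorafenib, the interaction and the average anti-PD1 effect, 1 in combination against vehicle and 2 in the average regorafenib effect. Among genes of at least 10 CPM, the correlation of regorafenib effects without and with anti-PD1 was 0.636 and that of anti-PD1 effects without and with regorafenib 0.292.

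Leaving out 1 library gave 0 genes in regorafenib against vehicle in each of 6 fits, 1 to 1421 in combination against vehicle, 0 to 432 in combination against anti-PD1 and 460 to 2048 in the average regorafenib effect. Lists changed numbered 7 to 18 in anti-PD1 against vehicle, 9 to 19 in combination against vehicle, 9 to 14 in combination against anti-PD1, 11 to 17 in combination against regorafenib, 9 to 22 in the average regorafenib effect and 5 to 13 in the average anti-PD1 effect. The correlations of fold changes ran from 0.41 to 0.599 for regorafenib and from 0.017 to 0.292 for anti-PD1; the cause was not tested.

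List calls whose test turned to the other direction did so with 1 library left out, and the range over the left-out libraries is given for each. Fibroblast genes in anti-PD1 against vehicle ran from -0.569 to 0.033, reversed without anti-PD1 1. In combination against regorafenib, M2-type macrophage genes ran from -1.062 to 0.154 and cell cycle genes from -0.478 to 0.189, reversed without regorafenib 1, and T cell genes from -0.746 to -0.053, dendritic cell genes from -0.867 to -0.048 and hypoxia genes from -0.059 to 0.616, reversed without combination 1, as were cell cycle genes (-0.063). In the interaction, cell cycle genes ran from -0.096 to 0.527, reversed without regorafenib 2, and skeletal muscle genes from -0.272 to 1.004, reversed without regorafenib 1 (0.023), where the median stayed positive and the test turned; the cause was not tested.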

Other observations

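The Y-linked covariate and the agreement by r or with only the regorafenib labels exchanged were chosen only after the results were seen. The other splits of the samples and the gene lists of this part were fixed before. In regorafenib against vehicle, all 18 macrophage genes were positive, with a median of 0.43 and values of 0.56 for Cd14, an endotoxin co-receptor, and 1.19 for the efferocytosis receptor Mertk (adjusted p of the list 0.00158, adjusted p = 0.566 with an estimated correlation), and the call ended without regorafenib 1 (0.32, adjusted p 0.0887), while the median was 0.22 without regorafenib 2 and 0.75 without regorafenib 3. Of 26 chemokine genes 25 were positive, among them Ccl4 (1.07) and Ccl3 (0.92), with a median of 0.76 (adjusted p 0.000835, adjusted p = 0.551 with an estimated correlation), and the call ended without regorafenib 1 (0.22, adjusted p 0.172). Of these genes 0 passed over all genes or adjusted over the list alone by edgeR.

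In combination against anti-PD1, 19 of 24 hypoxia genes were positive, with a median of 0.35 and 0 past the test, among them Vegfa (1.21), the gene of the endothelial growth factor, and the hexokinase gene Hk2 (0.71). The list had an adjusted p of 0.0139, and adjusted p = 0.998 with an estimated correlation. The call ended without anti-PD1 3 (0.18, adjusted p 0.133) or combination 1 (0.10, adjusted p 0.568), and the median was 0.57 without combination 3. With the Y-linked covariate the median was 0.098 and the call was lost (adjusted p 0.129). Xist, the RNA of the inactive X chromosome, measured 412.6 to 1405 CPM in the 12 libraries, beside Y-linked counts in all of them. The lists of mast cells, adipocytes, keratinocyte differentiation, kinases inhibited by regorafenib, stress and unfolded protein response, and immediate early and heat shock genes passed in 0 of 8 comparisons by camera, with smallest adjusted p-values of 0.335, 0.0885, 0.0714, 0.157, 0.0661 and 0.103.

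Chance in the grouping is unlikely for the genes of the average regorafenib effect and for the agreement of the regorafenib effects. A set of 100 groupings cannot exclude it. For the genes 1 of 100 splits, the real one, gave as many as 1610, and the highest other gave 217. For the agreement 1 of 100 regroupings gave a covariance as large as 0.1565, and the highest other was 0.1381. With only the regorafenib labels exchanged, the highest other covariance was 0.1421 (1 of 100 as large), and by r 3 of 100 were as large as 0.5684, the highest 0.6395. Chance cannot be excluded for the agreement of the anti-PD1 effects (24 of 100, 0.03158 against 0.1287), or for the lists of the average regorafenib effect (62 of 100, 14 against 23) and the average anti-PD1 effect (99 of 100, 3 against 25). For the genes of the interaction and of the average anti-PD1 effect the real count is 0, so 100 of 100 splits give as many in each and this test says nothing about chance. Other splits gave up to 2048 and 1253 genes there. Each comparison of 3 against 3 has 10 splits, too few for a share under 0.05. Among these, the genes of regorafenib against vehicle numbered 1 against a highest other of 0 (1 split as large), of combination against vehicle 1246 against 0 (1), and of combination against anti-PD1 326 against 0 (1). In anti-PD1 against vehicle (highest other 0) and combination against regorafenib (highest other 1467) the real count is 0, so 10 of 10 splits give as many by design. The split with 1467 sets regorafenib 1, regorafenib 2 and combination 3 against regorafenib 3, combination 1 and combination 2. These libraries had Y-linked counts of 32.14, 41.68 and 34.59 CPM against 18.09, 18.34 and 21.61 CPM. A role of host-cell share in this split was not tested. The split with 1253 holds the same parting and also sets vehicle 2, vehicle 3 and anti-PD1 3 against vehicle 1, anti-PD1 1 and anti-PD1 2. The lists numbered 21 against 20 (1 split as large) in regorafenib against vehicle, 11 against 23 (8) in anti-PD1 against vehicle, 14 against 22 (7) in combination against vehicle, 9 against 24 (9) in combination against anti-PD1 and 10 against 22 (9) in combination against regorafenib.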
